A study of Homo sapiens with 12 samples.

How the data were processed

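ATAC-seq, which cuts open chromatin with a transposase and sequences the fragments, was run on K562 cells, a human line from a chronic myeloid leukaemia. The labels give 12 samples in 6 groups of 2. The knockout series comprised cells carrying the CRISPR/Cas9 vector alone (EV), cells with silencer 1 deleted (S1KO, titled FGF18 in the labels), cells with silencer 2 deleted (S2KO) and cells with both deleted (DKO), at 200000 cells per library. The drug series comprised wild-type cells given 0.1% DMSO for 72 h (DMSO_72h) or GSK343 at 5 µM with X5050 at 100 µM for 72 h (GR_72h), at 50000 cells per library. GSK343 inhibits EZH2, the enzyme that writes H3K27me3, and X5050 inhibits the repressor REST.

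Per the submitters' processing notes, the tools were Trim Galore 0.6.6, Bowtie2 2.3.5.1, SAMtools 1.10, Picard 2.27.5-4, deepTools 3.4.3 and MACS2 2.2.7.1, and the build was hg19. Their roles and settings, including any shift of reads to the transposase cut site, are not given in the sources used here. The deposited data used here were 6 narrowPeak lists, 1 per group. Per the file headers, the 4 lists of the knockout series were each called on merged replicates, and the 2 lists of the drug series carry no such header. All 6 lists hold coordinates that fit hg19. Each row gives the peak's interval, the authors' fold enrichment over local background (a ratio), the authors' −log10 p and −log10 q, and a summit offset in bp. These values are the authors' own, and as such they served only to rank, filter or describe peaks within a list. The pileups and backgrounds decoded from them, described below, were compared between lists.

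Peaks on chromosomes 1 to 22 and X were used, which left out 1 row per list. No rows overlapped within a list. A peak counted as shared when it overlapped a peak of the other list by at least 1 bp, and otherwise as not called there. Shares carry Wilson 95% intervals that cover counting error only. With 1 list per condition there is no spread between replicates, so no test between conditions was made and no p-value is given. The pair of control lists, EV and DMSO_72h, served as a yardstick for lists that differ without a knockout or drug, although it also differs in cell number, vector and experiment.

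Depth was read from the peak rows, because total read counts were not used here. A peak's fold and −log10 p together fix a whole-number summit pileup (the number of extended reads over the summit) and a local background, if fold is (pileup + 1)/(background + 1) and p is the upper Poisson tail. This form matched 100% of the rows of every list within a relative error of 0.001 in −log10 p. The lowest background of a list stands for its depth relative to the other lists. Smallest peak width was 200 bp in all 6 lists. For shared peaks whose control pileup was at least 30, the ratio of pileups was divided by the ratio of backgrounds, put on a log2 scale and centred on its median within deciles of control pileup. A value of 0 is thus the genome-wide median of peaks of like strength. On simulated data, pileups drawn from the real lists came back exactly in 99.4% of 20000 peaks for S1KO and in 100% for GR_72h, and all dropped peaks of a simulated list were found. A simulated step on chromosome 5 among 300 peaks was placed within 1 Mb in 87% of 100 runs. That was a single step near the middle of uniformly spread peaks. The real steps had far fewer peaks before them than after, so the 87% need not hold for their place.

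Regions of the 4 knockout-series lists were merged into a union and counted by the lists that call them, genome-wide and on chromosome 5 from 160 to 180 Mb, an interval chosen beforehand from general knowledge of where FGF18 lies, and wide enough not to depend on the build. EV peaks with these patterns were also counted by strength, a count added after the data were examined. Losses were counted by decile of −log10 q in the control list and in 1 Mb windows with at least 20 control peaks. Overlap of losses between knockouts was set against independent lists, against independent losses within strength deciles, and against 100 simulated pairs of unchanged lists that share the EV list. The regions named follow a rule set before the data were examined: per comparison the 5 lost and 5 gained regions of highest −log10 q, up to 10 regions on chromosome 5 that follow the pattern of a silencer, and the 5 windows at either end of the range. Other regions were chosen after their values were seen, and the text says so. The pileup ratios were likewise added after the data were examined.

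An annotation of hg19 was not used here, and the gene table used has the assembly GRCh38.p14. The gene table was therefore not placed on the peaks, and the planned shares of promoters and the gene lists were not made. The gene table served only for the order of neighbouring genes. The alternatives tried were a reciprocal overlap of 50%, summits no more than 200 bp apart, a −log10 q of at least 5 in both lists or in the counted list only, lists of equal length, and, added after the data were examined, depth-matched lists. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots with matplotlib 3.10.9.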

Results

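The data were 6 lists of open chromatin peaks from K562 cells, 1 for each group of 2 samples. They address how the accessible genome differs after deletion of either or both of 2 silencers assigned to FGF18, a fibroblast growth factor gene, and after joint inhibition of EZH2 and REST, which bear on silencing by H3K27me3 and by a neuronal gene repressor. In the gene table of GRCh38.p14, FGF18 on chromosome 5 lies between NPM1, the nucleophosmin gene, and SMIM23, with TLX3 and RANBP17 beyond NPM1. Coordinates below are those of hg19, and the gene table was not placed on them.

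The number of peaks differed widely between lists. EV had 94913 peaks, S1KO 123766, S2KO 100889 and DKO 108464, against 63203 for DMSO_72h and 30253 for GR_72h. Peaks covered 48.5 Mb in EV, 60.9 Mb in S1KO, 50.6 Mb in S2KO, 55.8 Mb in DKO, 30.4 Mb in DMSO_72h and 13.2 Mb in GR_72h. Background level, which tracks depth, was 2.32 reads in EV, 2.85 in S1KO, 2.61 in S2KO, 2.72 in DKO, 2.17 in DMSO_72h and 2.272 in GR_72h. Peak number in the knockout series thus followed the order of background, whereas GR_72h had fewer peaks than DMSO_72h at 1.05 times its background. Counting only peaks whose summit pileup was at least 10 times the background level of their list left 61554 in EV, 72045 in S1KO, 61340 in S2KO, 65454 in DKO, 44611 in DMSO_72h and 20003 in GR_72h. Local background can exceed that level, so some of these peaks are weak by the authors' fold.

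**Figure D1:**
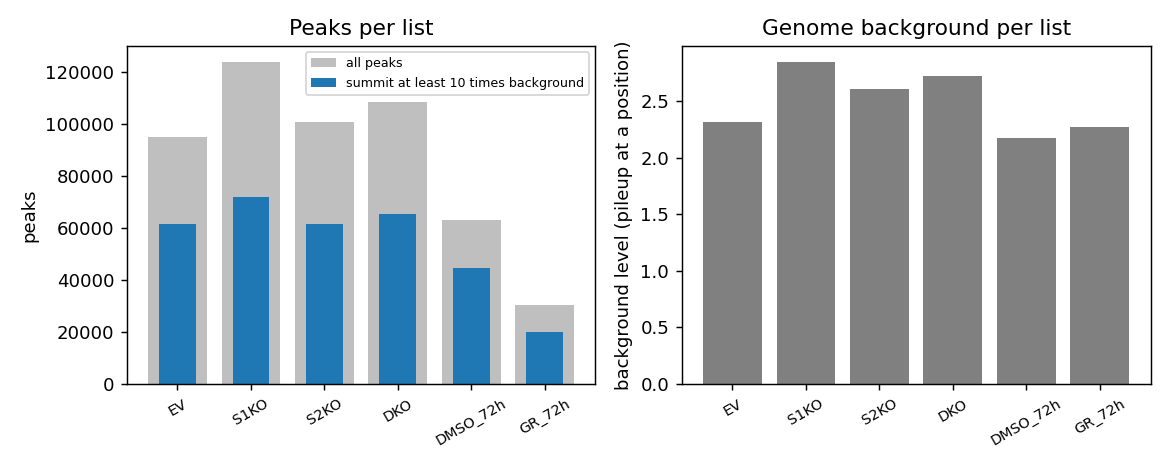
Left, peaks per list, with all peaks in grey and those whose summit pileup is at least 10 times background in blue; right, background level per list, as pileup at a position. GR_72h has 30253 peaks against 63203 in DMSO_72h although its background level is 1.05 times that of DMSO_72h.

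Combined inhibition of EZH2 and REST went with a much shorter list. Of the 63203 DMSO_72h peaks, 38369 were not called in GR_72h, or 60.7% (95% interval 60.3 to 61.1). Of the 30253 GR_72h peaks, 3832 were not called in DMSO_72h, or 12.7% (12.3 to 13.0). With both lists at the length of the shorter, 31.0% of DMSO_72h peaks and 25.5% of GR_72h peaks were not shared instead. The share of GR_72h peaks not called in DMSO_72h ranged from 6.28% to 38.6% over the settings tried, the highest with a reciprocal overlap of 50%. The pair of control lists, EV and DMSO_72h, gave 45.5% of EV peaks not called in DMSO_72h and 14.0% in the other direction. At a common length of 30253 peaks, EV and DMSO_72h differed by 21.6% and 20.2%, and pairs within the knockout series by 10.6% to 14.0%.

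Peaks not called in GR_72h were mostly the weaker ones. In the lowest decile of −log10 q within DMSO_72h, 93.9% were not called in GR_72h, in decile 5 it was 80.3%, in decile 8 it was 30.1%, and in decile 10 it was 1.84%, or 116 of 6321 peaks. All 116 of these were called in EV. Within decile 8, the narrowest 25% of peaks (245 to 422 bp) was missing in 45.5% of cases and the widest 25% (760 to 2340 bp) in 10.8%. The control pair showed the same gradient in decile 8, from 17.4% to 2.70%. Of DMSO_72h peaks called in all 4 knockout-series lists, 51.5% were not called in GR_72h, against 54.2% expected from their strength. Of the 4934 called in none of these lists, 97.2% were not called, against 87.2% expected.

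The strongest region lost with the inhibitors lay on chromosome 11 from 875760 to 876505, with a −log10 q of 89.6 in DMSO_72h. The others were on chromosome 1 from 211395522 to 211396359 (86.7), chromosome 8 from 141703362 to 141704274 (85.6), chromosome 12 from 6362252 to 6362853 (75.7) and chromosome 2 from 75089330 to 75090084 (75.6). All 5 were called in every list other than GR_72h. Gained regions ranked lower within their own list, the strongest at 4050 of 30253 in GR_72h, against 1172 of 63203 in DMSO_72h for the strongest loss. The strongest was on chromosome 13 from 100784387 to 100784704, at a −log10 q of 27.2 in GR_72h. Next came chromosome 1 from 21621486 to 21621853 (25.5), chromosome 3 from 57094431 to 57094770 (24.4), chromosome 6 from 31782023 to 31782751 (23.4) and chromosome 11 from 119089190 to 119089528 (22.6). Of these, 4 were also called in all 4 knockout-series lists, and the chromosome 6 region was called in GR_72h only. Among all 3832 gained peaks, 1325 (34.6%) were called in all 4 knockout-series lists and 1350 (35.2%) in none of them. No peak of the strongest decile of GR_72h was a gain (0 of 3026).

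Across 1281 windows of 1 Mb, the median share of DMSO_72h peaks not called in GR_72h was 61.4%. The highest was 90.0% on chromosome 1 from 175 to 176 Mb, followed by 88.0% on chromosome 19 from 43 to 44 Mb, 87.5% on chromosome 1 from 30 to 31 Mb, and 87.0% on both chromosome 12 from 106 to 107 Mb and chromosome 18 from 10 to 11 Mb. The lowest was 31.9% on chromosome 16 from 2 to 3 Mb, with 32.1% on chromosome 2 from 128 to 129 Mb, 32.6% on chromosome 19 from 58 to 59 Mb, 32.6% on chromosome 12 from 120 to 121 Mb and 32.8% on chromosome 19 from 48 to 49 Mb. In the 5 highest windows the number not called was at most 1.31 times that expected from peak strength. In the 5 lowest it was 0.686 to 0.871 times that expected.

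**Figure D2:**
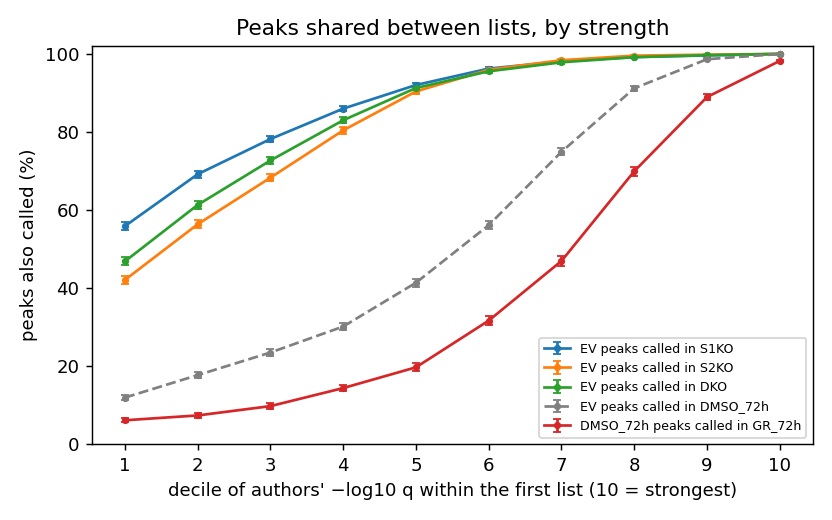
Percent of peaks of the first list that were also called in the second, by decile of the authors' −log10 q within the first list (10 is the strongest), with Wilson 95% intervals for counting error. In decile 8, 69.9% of DMSO_72h peaks were called in GR_72h, against 91.1% of EV peaks in DMSO_72h and over 99% of EV peaks in each knockout.

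Deletion of silencer 1 left most EV peaks in place and went with many additional peaks. In S1KO, 12.6% of EV peaks were not called (12.4 to 12.8, 11959 peaks), and 33.3% of S1KO peaks were not called in EV (33.0 to 33.5, 41195 peaks). Cutting S1KO to the length of EV made the directions nearly equal, at 19.6% and 20.4%. Loss was concentrated among weak peaks, at 44.1% in the lowest decile of EV and 7 of 9492 peaks in the highest. S1KO had the highest background of the 6 lists. The share of EV peaks lost was 21.0% with a reciprocal overlap of 50% and 7.80% among EV peaks with a −log10 q of at least 5.

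The strongest EV regions missing from S1KO were on chromosome 5 in 4 of 5 cases. They lay from 89854156 to 89855009 (−log10 q 147 in EV), 119848329 to 119849135 (117), 105581746 to 105583011 (93.9) and 126408964 to 126409401 (92.6), and the remaining region was on chromosome 18 from 23036228 to 23036776 (95.04). All 5 were called in DMSO_72h, so wild-type cells also held them. The chromosome 18 region lies in a segment of lowered pileup in S1KO, described under other observations. The strongest gained regions were on chromosome 1 from 36866331 to 36867377 (108 in S1KO), chromosome 4 from 66106911 to 66107931 (105), chromosome 5 from 169659752 to 169660915 (103), chromosome 7 from 121263182 to 121263878 (93.5) and chromosome 2 from 56070248 to 56070814 (86.1). These 5 were likewise all called in DMSO_72h, so EV was the control list without them. The gained region of chromosome 5 was called in S1KO, DKO, DMSO_72h and GR_72h and not in EV or S2KO.

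Deletion of silencer 2 gave the list nearest to EV in length. In S2KO, 16.9% of EV peaks were not called (16.7 to 17.2), and 21.3% of S2KO peaks were not called in EV (21.1 to 21.6). At equal length these were 18.5% and 18.1%, with the larger share now on the EV side. Among peaks with a −log10 q of at least 5 in the counted list they were 10.5% and 13.2%. The 5 strongest losses included 3 on chromosome 5, from 179740645 to 179741118 (−log10 q 122 in EV), 105581746 to 105583011 (93.9) and 40052666 to 40053369 (87.2). The others were on chromosome 13 from 70257877 to 70258695 (113) and chromosome 12 from 72971914 to 72972510 (96.5). The 5 strongest gains included 3 on chromosome 19, from 58513660 to 58514401 (87.6 in S2KO), 23185440 to 23186284 (85.3) and 23299511 to 23300312 (82.1). They also included chromosome 5 from 19287754 to 19289113 (82.6) and chromosome 12 from 89238223 to 89238656 (76.3), which was called in S2KO and DKO only. DMSO_72h called 4 of the 5 losses and 3 of the 5 gains, and not the strongest gain.

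Deletion of both silencers gave intermediate shares. In DKO, 15.3% of EV peaks were not called (15.1 to 15.5), and 26.5% of DKO peaks were not called in EV (26.2 to 26.7), or 19.2% and 20.04% at equal length. The share of EV peaks lost was 23.1% with a reciprocal overlap of 50% and 9.44% among EV peaks with a −log10 q of at least 5. The strongest losses were the S1KO regions of chromosome 5 at 89854156, of chromosome 18 at 23036228 and of chromosome 5 at 126408964, then chromosome 8 from 8085003 to 8086828 (−log10 q 84.2 in EV) and chromosome X from 127011723 to 127012544 (77.4), the last called in EV only. The regions of chromosomes 18 and 8 lie in segments lowered as a whole in S1KO and DKO, described under other observations. The strongest gains were chromosome 9 from 631309 to 632111 (114 in DKO), the regions of chromosome 4 near 66106907, of chromosome 5 near 169659713 and of chromosome 1 near 36866316 that S1KO also gained, and chromosome 2 from 130075836 to 130076949 (92.4). DMSO_72h called 4 of the 5 losses and 4 of the 5 gains, and not the region of chromosome 9. Of the DKO peaks, 16.0% were not called in S1KO, the longer list, and 24.2% not in S2KO. With each pair at equal length these were 19.7% and 20.8%. At a common length of 30253 peaks the order turned, at 13.4% against S1KO and 12.7% against S2KO. S1KO lacked 14.2% of S2KO peaks and S2KO lacked 30.9% of S1KO peaks, or 20.1% and 21.3% at equal length.

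Chromosome 5 held more of the strong peaks missing from the knockouts than its share of strong EV peaks. Of the 47 EV peaks in the 2 strongest deciles that S1KO lacked, 12 were on chromosome 5 (25.5%, 15.3 to 39.5), where 2.14 corresponded to its share of those deciles. In S2KO it was 7 of 27 against 1.23, and in DKO 8 of 38 against 1.73. In GR_72h, 35 of 817 missing DMSO_72h peaks of the 2 strongest deciles were on chromosome 5, against 36.8. Chromosome 13 also stood out, with 6 against 0.723 in S1KO, 5 against 0.415 in S2KO and 7 against 0.585 in DKO. Chromosome 2 had 8 against 3.12, 4 against 1.79 and 5 against 2.52 in the same order. Among knockout peaks of the 2 strongest deciles not called in EV, chromosome 5 was nearer its share, with 4 of 55 against 2.57 in S1KO, 1 of 36 against 1.60 in S2KO and 7 of 87 against 4.11 in DKO. Chromosome 13 had 5 against 0.815, 3 against 0.541 and 6 against 1.31 of these gains. Chromosome 19 had 11 of the 36 in S2KO against 2.45, and chromosome 7 had 12 of the 87 in DKO against 4.68. These chromosomes were chosen after their values were seen. The 3 knockouts were compared with the same EV list, and some missing peaks recur, so their counts are not separate findings. In the strongest decile, S1KO also lacked all 3 EV peaks missing from DKO and 2 of the 5 missing from S2KO. Of the missing chromosome 5 peaks named above, that at 179740645 lies in the interval chosen beforehand for FGF18. Those at 40052666, 89854156, 105581746, 119848329 and 126408964 lie outside it.

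The union of the knockout series held 153826 regions, of which 69895 (45.4%) were called in all 4 lists. A region deleted with silencer 1, or open only while it is present, would be called in EV and S2KO only, a pattern shown by 2012 regions. The matching pattern for silencer 2, EV and S1KO only, was shown by 3136 regions. The pattern that no shared deletion gives, EV and DKO only, was shown by 1664. Regions called in EV alone numbered 5736. The terms silencer 1 pattern and silencer 2 pattern refer to loss only. A region that opens on loss of silencer 1 would instead be called in S1KO and DKO only. For silencer 2 it would be called in S2KO and DKO only. No shared deletion gives the pattern S1KO and S2KO only. Among regions absent from EV, 21246 were in S1KO only, 10933 in DKO only, 7299 in S2KO only, 8164 in S1KO and DKO only, 4238 in S1KO and S2KO only, 2271 in S2KO and DKO only and 6773 in all 3 knockouts. With all 4 lists at 94913 peaks, the S1KO-only number was 8642 and that in S1KO and DKO only was 4077. Those in S2KO and DKO only numbered 2396, and those in S1KO and S2KO only 2453. The order of the silencer patterns turned at that length, with 3438 regions in EV and S2KO only, 2433 in EV and S1KO only and 2170 in EV and DKO only, and EV alone had 8866.

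**Figure D3:**
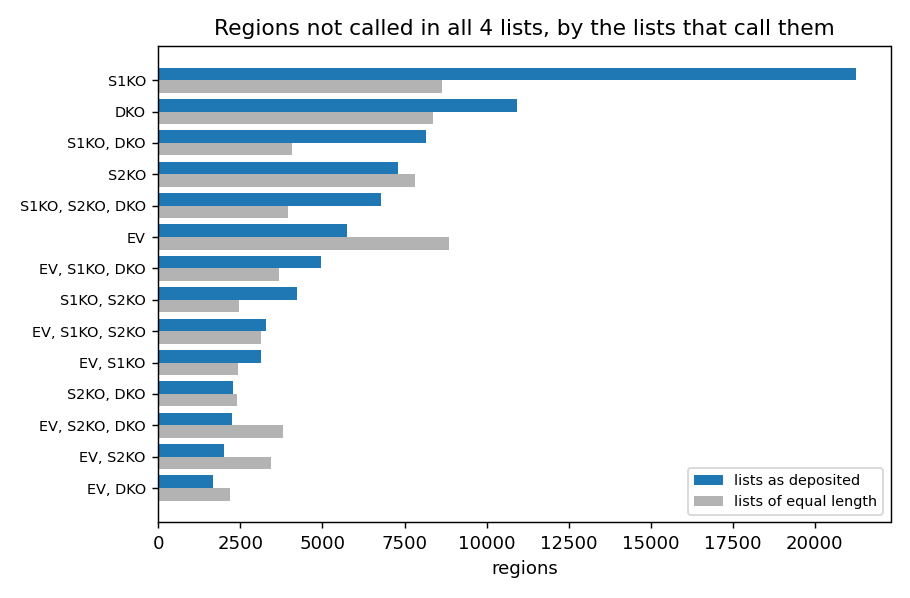
Number of regions called in some but not all of EV, S1KO, S2KO and DKO, by the lists that call them, for the lists as deposited (blue) and at equal length (grey). Regions called in S1KO only fall from 21246 to 8642 at equal length.

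EV peaks missing from 2 knockouts at once were frequent. S1KO and DKO jointly lacked 7819, against 1829 for independent lists, 4242 for independent losses within strength deciles and 6996 (range 6896 to 7113) in simulated unchanged lists that share EV. S1KO and S2KO jointly lacked 7520, against 2022, 4717 and 7480 (7382 to 7569), which lies within the simulated range. S2KO and DKO jointly lacked 9045, against 2455, 5769 and 8686 (8578 to 8791). The simulation drew around the EV pileups as if they were true levels, so it leaves out the sampling error of EV itself. A count above its range therefore does not by itself show real joint loss. The simulation also dropped exactly the weakest draws, whereas real losses reached some strong peaks. A count within its range therefore does not show that the lists are unchanged. EV is 1 list and could not be split, so part of any excess can come from the shared list. Segments of chromosomes 8 and 18 had lower pileup in both S1KO and DKO, as described under other observations. They may add to the joint losses of those lists, which were not counted without them.

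The interval of chromosome 5 chosen beforehand, from 160 to 180 Mb, held 1090 regions, 441 of them in all 4 lists. The silencer 1 pattern was shown by 17 regions, the silencer 2 pattern by 37 and the EV and DKO only pattern by 13. Among regions absent from EV, 220 were in S1KO only (20.2% of the interval's regions, against 13.8% genome-wide). Those in S1KO and DKO only numbered 65 (5.96% against 5.31%). Those in S2KO and DKO only numbered 6 (0.55% against 1.48%), and those in S1KO and S2KO only 27 (2.48% against 2.76%). At equal length S1KO only had 94 of 893 regions, against 8642 of 130620 genome-wide. The strongest of the 54 regions with a silencer pattern lay below the EV median in −log10 q. With the silencer 1 pattern they were 178281327 to 178281824 (14.8), 170890005 to 170890239 (11.8), 174519591 to 174520153 (10.8), 173312379 to 173312925 (9.28) and 162710620 to 162711415 (8.07). With the silencer 2 pattern they were 179453372 to 179453691 (11.8), 168308855 to 168309125 (9.88), 179514080 to 179514299 (9.07), 171177217 to 171178173 (8.07) and 179186965 to 179187460 (7.27). Genome-wide, the silencer 1 and silencer 2 patterns were shown by 1.64% and 1.47% of EV peaks in decile 5 (10.8 to 15.1), 3.14% and 3.603% in decile 4 (8.07 to 10.8) and 3.88% and 6.71% in decile 3 (5.98 to 8.07). Counted as EV peaks, the interval had 17 with the silencer 1 pattern, 39 with the silencer 2 pattern and 14 with the EV and DKO only pattern. Their strength gave an expected 15.03, 24.1 and 13.04. The silencer 2 pattern requires absence from both S2KO and DKO. Shared peaks towards the chromosome end, beyond the DKO step described below, had median log2 pileup ratios of −0.18 in S2KO and −0.23 in DKO. In S1KO the median there was 0.012. The expected numbers do not allow for such a regional lowering. The excess of 39 over 24.1 therefore does not by itself show regions that are open only while silencer 2 is present.

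Peak number changed along this interval. From 167 to 171 Mb, EV had 117 peaks, S1KO 184, S2KO 109 and DKO 161, or 1.57, 0.932 and 1.38 times EV. From 171 Mb to the chromosome end S1KO had 753 peaks, S2KO 528 and DKO 537, or 1.34, 0.940 and 0.956 times EV. Genome-wide the ratios were 1.30, 1.06 and 1.14. The division at 171 Mb was taken from the step in summit pileup of DKO, after the values were seen, so the 2 are not separate findings of its place. In shared peaks of DKO, the best single step fell between peaks at 170961245 and 171057236, with a median log2 ratio to EV of 0.11 over 65 peaks before it (bootstrap 95% interval over peaks 0.01 to 0.27) and −0.23 over 311 peaks after it (−0.28 to −0.19). Over the same 2 parts S2KO had medians of −0.078 and −0.18, S1KO −0.0049 and 0.012, and DMSO_72h −0.12 and 0.0074. The best single step of S2KO lay nearer the centromere, between peaks at 167696549 and 167913431, with only 11 shared peaks before it. In the 2 Mb before the DKO step the DKO median was 0.27 (0.14 to 0.40), so that step sets a raised stretch beside a lowered one. Each step was placed where the contrast was largest, and the bootstrap intervals do not allow for that choice.

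**Figure D4:**
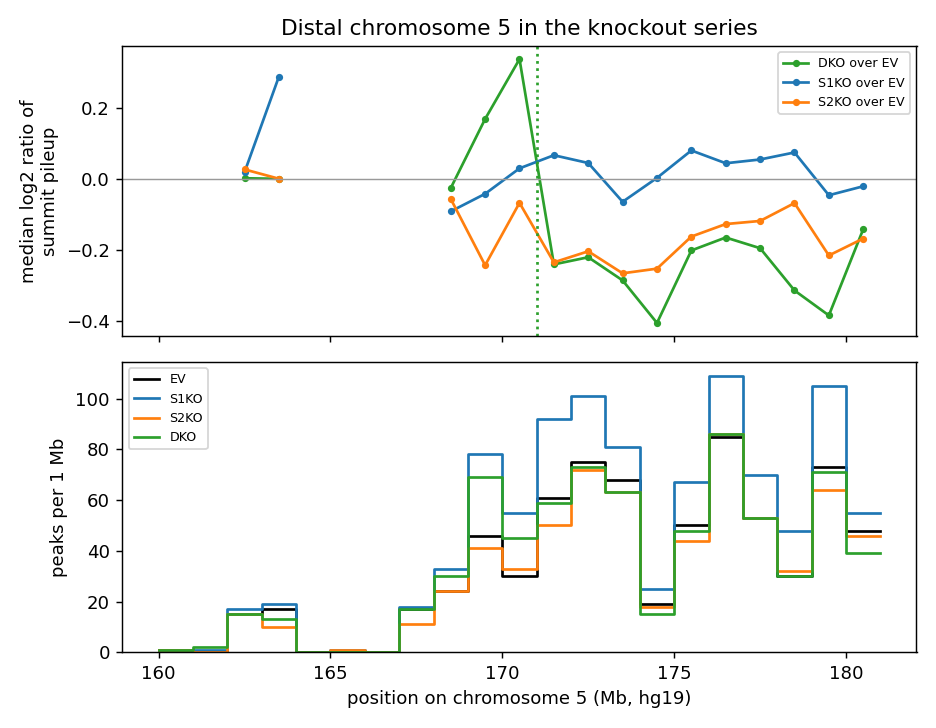
Chromosome 5 from 160 Mb (hg19). Top, median log2 ratio of summit pileup to EV at shared peaks per 1 Mb, for windows with at least 5 such peaks, centred on the genome; the dotted line marks the step in DKO. Bottom, peaks per 1 Mb in the 4 lists. Beyond the step the median is −0.23 in DKO, −0.18 in S2KO and 0.012 in S1KO.

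Losses were uneven along the genome. Of 1640 windows of 1 Mb with at least 20 EV peaks, the median share not called was 11.6% in S1KO, 16.7% in S2KO and 14.5% in DKO. The window of chromosome 2 from 141 to 142 Mb held 21 EV peaks and none in the other 5 lists. Chromosome 16 from 59 to 60 Mb held 21 EV peaks, of which S1KO called 2, S2KO 3, DKO 1 and DMSO_72h 2. The next windows in S1KO were chromosome 2 from 143 to 144 Mb (82.1%), chromosome 8 from 39 to 40 Mb (18 of 24 not called) and chromosome 4 from 138 to 139 Mb (15 of 20). In S2KO they were chromosome 4 from 138 to 139 Mb (14 of 20 not called), chromosome 13 from 67 to 68 Mb (53.6%) and chromosome 5 from 88 to 89 Mb (50.98%). In DKO they were chromosome 18 from 22 to 23 Mb (82.1%), chromosome 8 from 58 to 59 Mb (60.9%) and chromosome 14 from 25 to 26 Mb (58.3%). Some of these windows lie in stretches where shared peaks were lower as a whole in the same knockout, described under other observations. They are the windows of chromosomes 8 and 4 in S1KO, of chromosome 13 in S2KO and of chromosome 18 in DKO. Chromosome 2 from 140 to 150 Mb, which holds both windows named on it, also had a lowered median log2 pileup ratio in S1KO. It was −0.23 over 57 shared peaks. At the other end, 20 windows lost no EV peak in S1KO, 4 in S2KO and 20 in DKO, so those named are part of a tie in S1KO and DKO. From strength, 1.44 to 2.85 losses were expected in the S1KO windows named, 1.87 to 7.25 in those of S2KO and 2.303 to 4.35 in those of DKO. They included chromosome 7 from 74 to 75 Mb, chromosome 1 from 222 to 223 Mb, chromosome 12 from 26 to 27 Mb, chromosome 3 from 23 to 24 Mb and chromosome X from 148 to 149 Mb in S1KO. In S2KO they included chromosome 3 from 20 to 21 Mb and chromosome 10 from 34 to 35 Mb besides the windows of chromosomes 1 and 12, and chromosome 19 from 53 to 54 Mb lost 1 of 49. In DKO they included chromosome 19 from 57 to 58 Mb, chromosome 2 from 66 to 67 Mb and 3 windows of chromosome X, from 30 to 31, 69 to 70 and 120 to 121 Mb.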

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

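The alternatives were fixed before the data were examined, apart from depth matching, which was added afterwards. The interval for counting error is narrow, so 42 of 48 shares left it; the other 6 were depth-matched ones. At equal length the gap between directions was smaller, and its sign stayed in 3 of 4 comparisons and turned in S2KO. At a common 30253 peaks GR_72h lacked 31.0% of its control's peaks, the knockouts 10.6% to 13.8% and DMSO_72h 21.6% of EV peaks. Shares below follow the order EV peaks missing in the knockout, then knockout peaks missing in EV, and for the drugs DMSO_72h peaks missing in GR_72h, then the converse. With a reciprocal overlap of 50% they were 21.0% and 39.4% for S1KO, 23.1% and 27.7% for S2KO, 23.1% and 32.7% for DKO, and 70.6% and 38.6% for the drugs. With summits no more than 200 bp apart they were 17.5% and 36.7%, 21.0% and 25.7%, 19.99% and 30.0%, and 63.4% and 23.5%. With a −log10 q of at least 5 in both lists they were 9.91% and 30.5%, 13.8% and 17.5%, 12.1% and 24.0%, and 60.3% and 7.42%. With that limit on the counted list only they were 7.80% and 24.9%, 10.5% and 13.2%, 9.44% and 19.1%, and 55.5% and 6.28%. At equal length they were 19.6% and 20.4%, 18.5% and 18.1%, 19.2% and 20.04%, and 31.0% and 25.5%. Depth matching moved the share of S1KO peaks missing in EV to 32.8% and that of DKO peaks to 26.1%; it thins summits only and ignores the width a peak needs, so it may understate the effect of depth. With all 4 knockout-series lists at equal length, the regions numbered 8866 in EV only, 8642 in S1KO only, 3438 in EV and S2KO only, 3798 in EV, S2KO and DKO only, 4077 in S1KO and DKO only, 2453 in S1KO and S2KO only, and 3941 in the 3 knockouts only, and the other 8 patterns stayed within 1.5 times. Beyond what each definition or length itself changes, the cause was not tested. No paired analysis was possible because each condition has 1 list and its result comes from no test, and leaving out a replicate was likewise not possible. The shares of promoters and the gene lists were not run, for want of an hg19 annotation here.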

Other observations

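All tests in this part were chosen after the result was seen. Segments of several chromosomes differed in pileup between lists. On chromosome 8 from 0 to 45 Mb, shared peaks had a median log2 pileup ratio to EV of −0.32 in S1KO and −0.28 in DKO, with 88.1% and 85.9% of peaks below the genome median, against −0.01 in S2KO and −0.05 in the control list DMSO_72h. On chromosome 18 from 15 to 35 Mb the medians were −0.38, −0.40, −0.04 and −0.11 in the same order, and on chromosome 11 from 0 to 10 Mb they were 0.21, 0.21, 0.0072 and 0.0040. Other segments were lowest in 1 knockout: chromosome 4 from 70 to 190 Mb had a median of −0.24 in S1KO, −0.03 in DKO and 0.05 in DMSO_72h, chromosome 6 from 140 to 170 Mb had −0.20 in DKO, −0.01 in S1KO and 0.0098 in DMSO_72h, and chromosome 5 from 0 to 45 Mb had −0.13 in S2KO, 0.04 in DKO and −0.05 in DMSO_72h. Within the chromosome 5 segment, from 0 to 10 Mb, DMSO_72h was lower than S2KO, at −0.19 against −0.08.

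Among bins of 10 Mb with at least 20 shared peaks, 22 of 292 were lower by at least 0.2 (log2) in S1KO, 13 of 292 in DKO and 3 of 293 in S2KO. The control list DMSO_72h had 11 of 293, which is below S1KO, near DKO and above S2KO. S1KO and DKO had 9 low bins in common, against 0.938 for independent sets, S1KO and S2KO 2 against 0.226, S2KO and DKO 1 against 0.0890, S1KO and DMSO_72h 1 against 0.829, and DKO and DMSO_72h 2 against 0.490. These comparisons share the EV list, so part of any excess can come from it. Most low bins common to S1KO and DKO are neighbours on chromosomes 8 and 18, where lowered segments are given above. Neighbouring bins are not independent, so the numbers for independent sets can be too low, and those common bins are no separate finding. Chromosome 13 from 60 to 70 Mb was low in all 3 knockouts, at −0.66 in S1KO, −0.39 in S2KO and −0.35 in DKO, and stood at −0.08 in DMSO_72h. Whether these segments differ in copy number was not tested. In the drug series, the bin with the highest ratio of GR_72h to DMSO_72h was chromosome 22 from 20 to 30 Mb, at 0.37 over 207 peaks. Relative to EV the same bin was at 0.12 in DMSO_72h, 0.11 in S1KO, 0.08 in S2KO and 0.06 in DKO.

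The drop from 63203 to 30253 peaks with the inhibitors was set against depth and against library enrichment. Lower depth would need a lower background in GR_72h, and the ratio of backgrounds was 1.05, which argues against it. A library with a lower share of reads in peaks would lower the strong peaks as a whole. The depth-scaled pileup of the strongest decile of DMSO_72h peaks had a median ratio of 0.475 in GR_72h, against 0.628 for EV peaks in DMSO_72h, a pair without the inhibitors. Enrichment of the library and closing of chromatin by the inhibitors cannot be told apart here, because each condition has 1 list and both would lower strong peaks; the biological explanation stays open and untested.

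The emptied window of chromosome 2 from 141 to 142 Mb was set against peak strength. It was picked for its losses in the knockouts, so those losses cannot test the choice, and the test rests on DMSO_72h. Of its 21 EV peaks DMSO_72h called 0, where 8.73 were expected from the rate among all EV peaks of their strength. Peaks picked for their absence from the knockouts can be called less often elsewhere at any strength. The expectation does not allow for that, so the comparison cannot decide whether weak peaks are the cause. If the peaks are specific to the EV cells, wild-type cells would lack them too, and the 0 called in DMSO_72h fits that. This is the same value again, and absence elsewhere is part of what specific means, so it is no separate test. The window of chromosome 16 from 59 to 60 Mb, also picked for its losses, had 2 of 21 called in DMSO_72h against 9.76 expected, with the same limit. The chromosome 2 window sets EV apart from all other lists. Whether EV gained its peaks or the other cells lost them cannot be told here. A difference that arose in the EV cells stays a hypothesis.

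The lower pileup on distal chromosome 5 was not particular to DKO: beyond the DKO step the median was −0.23 in DKO and −0.18 in S2KO. Other parts of chromosome 5 were raised, with 0.13 in S2KO from 130 to 140 Mb and 0.12 in DKO from 140 to 150 Mb. The best steps of DKO and S2KO differ in place, but that of S2KO is poorly fixed. It had 11 shared peaks before it, where the search required at least 10. From 169 to 170 Mb, before the DKO step, the median was 0.17 in DKO and −0.24 in S2KO. From 170 to 171 Mb it was 0.34 and −0.07. Among 154 tiles of 20 Mb, that from 160 to 180 Mb ranked 6 in DKO and 2 in S2KO. If EV were the odd list, the lists set against it would all be lower there, and the medians of 0.012 in S1KO and 0.0074 in DMSO_72h argue against that. A loss of copies would lower strong and weak peaks alike, and in DKO the stronger peaks exceeded the weaker by 0.13 (bootstrap 95% interval 0.04 to 0.23), but the lowered parts of chromosomes 8 and 18 showed such a gap too, so the test decides nothing. Copy number was not measured, and loss of copies and a regional change of accessibility cannot be told apart.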
